A study of Mus musculus with 4 samples.

How the data were processed

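Total RNA of the stomach was extracted with TRIzol, and 1 microgram was transcribed into digoxigenin-labelled cRNA with an Applied Biosystems chemiluminescent kit, per the labels' protocols. Each of the 4 arrays held a pool of RNA from 3 male mice, and groups and pool numbers were taken from the sample titles. The deposited table holds 1 log2 signal per probe and array. The authors' normalization, the log base and the rule behind blank cells are not given in the sources used here. In the values, the 4 arrays share the maximum of 21.2 and between 93.3% and 94.8% of an array's values also occur on another array, as quantile normalization would leave them. The log base is inferred from the range (6.73 to 21.2), and every difference and fold rests on it. Of 33012 probes, 12295 are blank on all arrays and 13475 on none. Blanks were more frequent for dim probes: where the other 3 arrays averaged under 10, between 20.0% and 32.5% of values were blank, and over 14 between 0.0244% and 1.38%. A blank was therefore not read as an absent transcript, and signal over background is unknown here.

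Probes were named through a table of the platform's annotation. Of 33012 probes, 14411 had 1 gene symbol, 247 had several and 18354 had none. Among the 13475 compared, the numbers were 7907, 102 and 5466. Probes with several symbols were left unnamed. Of all probes, 14402 matched the mouse reference annotation (assembly GRCm38.p6), which was used for chromosomes and gene order only, since no genome build is given for the array. It changed no symbol. No named gene that passed had more than 1 compared probe. Where a gene had several (219 of 7682 genes), lists and gene order used the probe with the highest mean.

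No further normalization was applied, because over the 13475 probes the medians of the arrays lay between 12.819 and 12.824. Over each array's own values the medians lay between 12.23 and 12.34. The strains were compared per probe with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with the mean-variance trend, 2 residual and 3.97 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all 13475 probes and a threshold of 0.05. No pseudocount and no filter on dim probes were used. Tested on simulated data for this comparison (13475 probes, 100 changed per size), the fit recovered 50% of changes of 1 log2 and 77% of changes of 2 log2, and 8 of its 135 calls were probes not changed.

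Enrichment on chromosome 17 was tested with Fisher's exact test over named probes. The share of small p-values in windows of 40 consecutive measured genes was compared with 10000 shuffles of the genes over all positions. Lists for the stomach's cell types, neighbouring tissues, the major histocompatibility region, hormones and metabolism were fixed before the data were examined. The 31 lists with at least 5 measured genes were tested with camera (preset correlation 0.01, and estimated) and fry, adjusted over lists. The 5 others were left untested: glucagon-related hormones (4 measured genes), T and natural killer cells (3), B and plasma cells (1), erythroid cells (1) and endocrine pancreas (0). Genes were named by a rule fixed at the same time: Glp1r, the 12 largest rises and 12 largest falls among probes that passed, had 1 symbol and whose pools did not overlap (23 higher and 17 lower), every list member that passed, up to 4 members per list by p, and 15 chromosome 17 genes by p. Chosen after their values were seen were Slc25a23, Pigr, Pum2, Tff2, H2-K1, Clps, Pnliprp2, Pla2g1b, Mb, Mylpf, the members of lists too small to test, the genes that bound stretches of chromosome 17, and the genes with blanks on some arrays.

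Alternatives were the replicate number as a block, quantile normalization, median centring, leaving out the probes below the median level, leaving out each pool, other variance models and thresholds, windows of 20 and 80 genes, and the mean over a gene's probes for lists. A fit that allowed 1 blank per probe was chosen after seeing the data. Probes with more blanks entered no comparison. Figures were drawn with matplotlib 3.10.9.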

Results

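Gene expression was measured in the stomach of male mice of 2 strains on single-colour mouse microarrays. One strain was wild-type C57BL/6J, a standard inbred laboratory mouse. The other was B6.CAST-17, a homozygous congenic strain, which by its name carries a chromosome 17 segment of CAST origin on the background of the first strain. Each strain was represented by 2 pools of RNA, each made from 3 animals, so 6 animals per strain entered the study on 4 arrays. Mice ate chow and were food deprived for 4 h before the stomach was taken. A value was given for 16954 and 16871 of the 33012 probes in congenic pools 1 and 2, and for 16320 and 16326 probes in wild-type pools 1 and 2. All 4 arrays had a value for 13475 probes, and these were compared. Across these probes, which are not independent replicates, Pearson's r was 0.991 between the congenic pools and 0.988 between the wild-type pools, and lay between 0.983 and 0.986 between strains. The number of arrays limits the precision of every comparison, and the p-values measure the spread between pools of 3 animals, not between single animals. Differences are congenic minus wild type on the log2 scale, ± SE, with n = 2 pools per strain throughout.

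The study's title concerns Glp1r, the receptor for the gut hormone glucagon-like peptide and a gene of chromosome 17. Its probe (591309) had a value on 1 of the 4 arrays, wild-type pool 1, where it was 10.08 on the log2 scale, above 13.3% of the values of that array. Both congenic pools and wild-type pool 2 had no value for it, so no difference between the strains was tested. The nearest genes measured on all arrays on either side were Glo1 and Tff2. Glo1, which encodes a glyoxalase that detoxifies methylglyoxal, was 1.65-fold higher in the congenic pools (0.72 ± 0.084; limma adjusted p = 0.03347). Glo1 did not pass when any 1 pool was left out (limma adjusted p between 0.05127 and 0.244). Tff2, a trefoil peptide of gastric mucus, differed by 0.14 ± 0.17 (limma adjusted p = 0.7198), and the sign changed without congenic pool 1 or wild-type pool 1. Of a list of 16 gut peptide hormones related to glucagon, with their receptors and processing enzymes, 4 were measured on all arrays and none of these passed. Vip differed by 0.30 ± 0.088, Sct by 0.16 ± 0.22, Vipr1 by 0.13 ± 0.23 and Pcsk1 by -0.075 ± 0.22.

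Between the strains, 64 of 13475 probes passed an adjusted p of 0.05 in limma, 39 higher and 25 lower in the congenic pools, and 42 of them differed at least 2-fold. Of the 64, 40 had a single gene name, 6 matched several genes and 18 had no gene name. Among the named, 20 were genes of chromosome 17, 10 belonged to the exocrine pancreas list, 3 to the skeletal muscle list and 1, Alb, to the liver list. The remaining 6 were Chil3, Actl6b, Hpx and Pigr, which rose, and Cd5 and Pum2, which fell. Chil3, a chitinase-like protein of macrophages and mucosa, rose 3.27-fold (1.71 ± 0.080, limma adjusted p = 0.001088). Pigr, the receptor that carries polymeric antibodies across epithelia, rose 2.32-fold. Hpx, the haem-binding plasma protein hemopexin, rose 2.82-fold, and Actl6b, a subunit of a neuronal chromatin-remodelling complex, rose 2.93-fold. Cd5, a T cell surface protein, fell by 1.25 ± 0.10, and Pum2, an RNA-binding repressor, fell by 0.92 ± 0.098. Of these 6, all but Chil3 lost the call without congenic pool 1 and without congenic pool 2. In each of the 64, both congenic values lay on one side of both wild-type values, as they did in 49.4% of all probes compared and would in 33.3% by chance. An unadjusted p under 0.05 was reached by 2127 probes, where 673.8 would be by chance. The count of 64 was 15 without congenic pool 1 (9 higher and 6 lower), 27 without congenic pool 2 (12 higher and 15 lower), 61 without wild-type pool 1 (33 higher and 28 lower) and 168 without wild-type pool 2 (141 higher and 27 lower). It was 20 when the dependence of the variance on the signal level was not modelled (13 higher and 7 lower). In a count chosen after the data were seen, of probes on which 1 array lay more than 1 log2 from each of the others while those lay within 0.5 of one another, wild-type pool 1 stood apart on 80 (74 of them lower), wild-type pool 2 on 22, congenic pool 1 on 21 and congenic pool 2 on 13. None of these probes was among the 64, and of the 80, 70 were among the 168 called without wild-type pool 2.

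The chromosome named in the congenic strain held a larger share of changed genes than the rest of the genome. On chromosome 17, 20 of 383 named probes passed (5.22%), against 20 of 7521 on the other chromosomes (0.266%). The odds ratio was 20.6, with a 95% interval of 10.4 to 40.8 (Fisher's exact test, two-sided, p = 1.771e-16, with genes taken as independent). At an unadjusted p under 0.01 the odds ratio was smaller, 4.67 (95% interval 3.47 to 6.23), with 69 of 383 probes against 338 of 7521. Of the 20 on chromosome 17 that passed, 8 rose and 12 fell. H2-Ob, the beta chain of an atypical class II molecule that tunes antigen loading, had the largest change among all named probes that passed, a 51.3-fold rise from 11.77 in wild type to 17.46 in the congenic pools (5.68 ± 0.23, limma adjusted p = 0.0005403). In the congenic pools the H2-Ob probe read above the class II gene H2-Aa (13.38) and above Cd74, an antigen presentation gene elsewhere (16.15). Whether the probe reads H2-Ob alone was not examined. Msh5, a meiotic recombination factor, rose 3.40-fold, Dynlt1b, a dynein light chain, 2.58-fold, and Pim1, a serine/threonine kinase, 2.19-fold. Srpk1, a kinase of splicing factors, rose 1.65-fold. D17H6S56E-5 fell by 2.42 ± 0.084 and Taf11, a subunit of the general transcription factor TFIID, fell by 2.40 ± 0.14. Decr2, a peroxisomal enzyme of unsaturated fatty acid breakdown, fell by 1.96 ± 0.12, and Enpp5 fell by 1.40 ± 0.090. Plin3, a lipid droplet coat protein, fell by 1.27 ± 0.095, and Mtch1, a mitochondrial outer membrane protein, fell by 1.23 ± 0.068. Vars, which charges the valine transfer RNA, fell by 1.20 ± 0.11, and Acer1, an alkaline ceramidase, fell by 1.03 ± 0.098. D17H6S56E-5, Vars and Msh5 were consecutive among the measured genes, with D17H6S56E-5 and Vars lower and Msh5 higher. Dynlt1b has near-identical copies and its values are uncertain, and whether probes lie over bases that differ between CAST and C57BL/6J was not examined. The count of 20 was 6 without congenic pool 1, 8 without congenic pool 2, 11 without wild-type pool 1, and 8 without the variance trend.

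**Figure D1:**
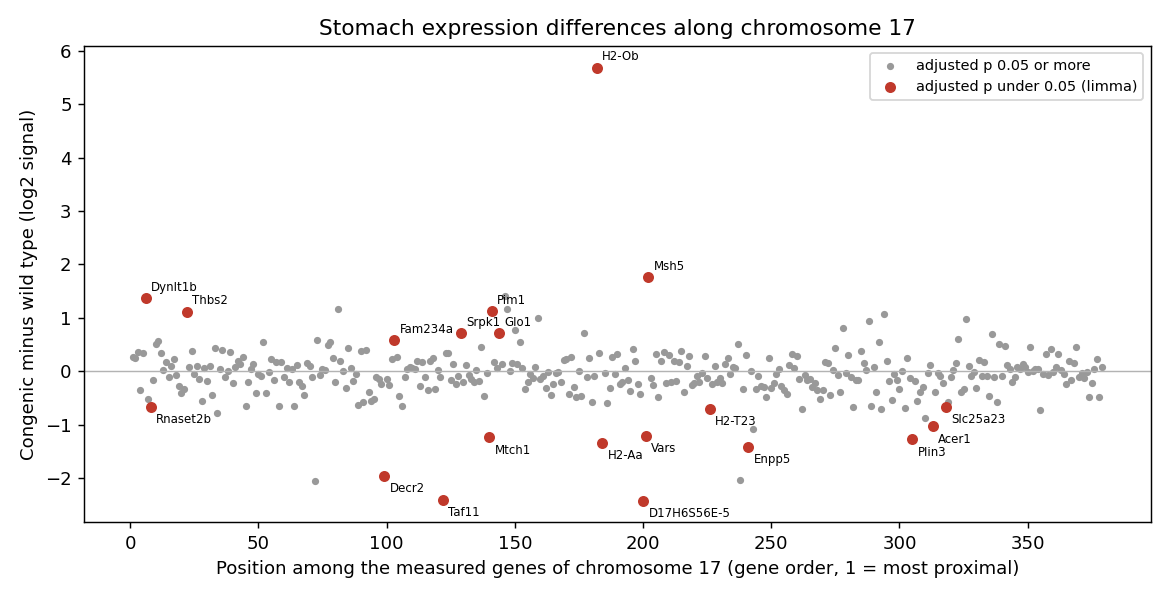
Difference between congenic and wild-type stomach (log2 signal, mean of 2 pools per strain) for each of the 379 measured genes of chromosome 17, in gene order; red points passed an adjusted p of 0.05 in limma and grey points did not. The 20 red points lie between position 6 (Dynlt1b) and position 318 (Slc25a23), and H2-Ob stands highest at 5.68.

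Genes with small p-values were more frequent on chromosome 17, where 18.0% of named probes had an unadjusted p under 0.01, than elsewhere (4.49%). Among runs of 40 consecutive measured genes, the highest share with an unadjusted p under 0.01 was 32.5% on chromosome 17 and at most 17.5% on any other, on chromosome 19. Windows on chromosome 17 above the 95th percentile of the highest shuffled window (22.5%) covered 2 stretches. The first ran from Tsc2 to Lta (147 measured genes, 24.5% with p under 0.01) and held Glo1 and the class II genes H2-Ob and H2-Aa. The second ran from Cnpy3 to Yipf4 (76 genes, 22.4%) and held Plin3 and Acer1. The outermost genes that passed were Dynlt1b, at position 6 of 379, and Slc25a23, at position 318. Shuffling genes over all positions gave a window as high as that of chromosome 17 with p = 0.0003 (permutation test, 10000 shuffles). Because the shuffles moved genes between chromosomes, they do not tell closeness within chromosome 17 from its higher share as a whole. The 2 stretches were picked by the same windows. Without congenic pool 2 the highest window was 20% (permutation p = 0.004995).

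**Figure D2:**
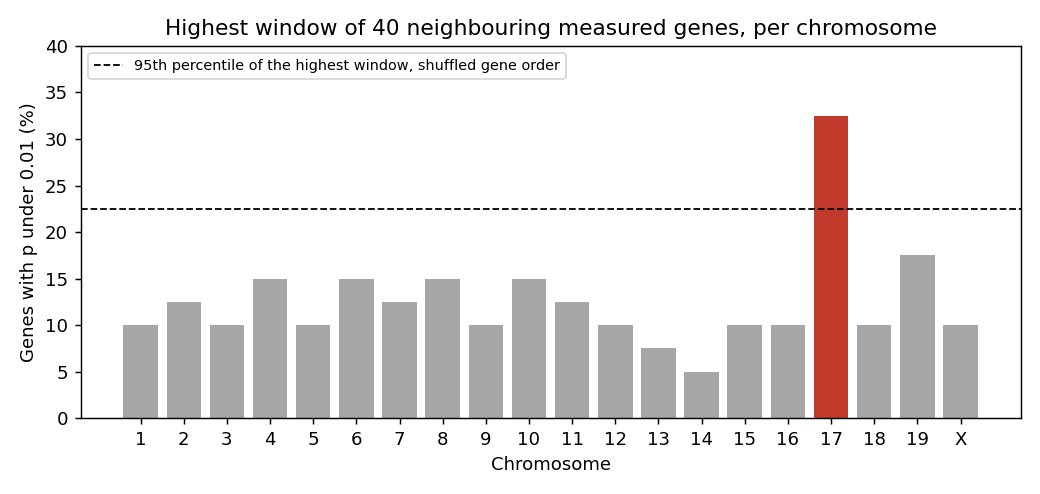
Highest share (%) of genes with an unadjusted p under 0.01 in any window of 40 consecutive measured genes, per chromosome; the dashed line is the 95th percentile of the highest window after shuffling gene order. Chromosome 17 reached 32.5%, above the line at 22.5%, and every other chromosome plotted stayed at or below 17.5%.

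The major histocompatibility region of chromosome 17 encodes antigen-presenting molecules among other proteins. Of a list of 45 of its genes, 17 were measured, of which 1 rose (H2-Ob), 2 fell (H2-Aa and H2-T23) and 14 did not pass. The list does not hold every gene of the region: D17H6S56E-5, Vars and Msh5, which passed, lie between its members H2-K1 and H2-M2 in gene order and are not in it. Adjusted over the list alone, 5 passed, 2 higher and 3 lower. H2-Aa, the alpha chain of a class II molecule, fell by 1.33 ± 0.081 (limma adjusted p = 0.002967), and H2-T23, a non-classical class I molecule, fell by 0.69 ± 0.079. H2-Ke6 (-0.48 ± 0.10) and H2-K1, a classical class I heavy chain (0.27 ± 0.076), passed adjusted over the list alone and not over all probes. The list showed no common direction (camera adjusted p = 0.9632; median -0.033, mean 0.23, test direction down). Its class I and class II genes resemble one another and their probes may share signal, while other members, such as Tnf and Ltb, belong to neither class. Without congenic pool 1, 1 rose and 0 fell over all probes in limma, with 2 higher and 2 lower adjusted over the list alone, and without any other single pool 1 rose and 1 fell. Antigen presentation genes elsewhere in the genome gave 0 of 9 past the threshold in limma, 1 with an unadjusted p under 0.05 and 0 adjusted over the list alone, with a median of 0.037. Among 8 measured metabolic genes of chromosome 17, Glo1 rose and Decr2 fell, and 3 passed adjusted over the list alone, with Cbs, an enzyme of sulfur amino acid metabolism, as the third (0.78 ± 0.13, limma adjusted p = 0.1141). This list's median (0.11) and mean (-0.019) differed in sign, and its test direction was up (camera adjusted p = 0.422).

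Genes of the exocrine pancreas, which makes digestive enzymes, were higher in the congenic stomach samples. Of 17 measured members, 10 rose, 0 fell and 7 did not pass, and 15 passed adjusted over the list alone, all higher. The elastase Cela2a rose 9.40-fold (3.23 ± 0.081, limma adjusted p = 0.0002302), Cela3b 8.52-fold, Reg1 8.16-fold, the chymotrypsinogen Ctrb1 7.20-fold and the carboxypeptidase Cpb1 5.62-fold. Cpa1, another carboxypeptidase, lay between Reg1 and Ctrb1. The amylase Amy2a5 rose 2.21-fold, the trypsinogens Prss1 and Prss3 1.98-fold and 1.66-fold, and the lipase Cel 1.77-fold. Pla2g1b (0.42 ± 0.12) passed adjusted over the list alone and not over all probes, and Clps (-0.086 ± 0.14) and Pnliprp2 (-0.22 ± 0.11) passed neither. The list's median was 0.99 (camera adjusted p = 2.045e-22 with a preset correlation; adjusted p = 0.258 with an estimated correlation; fry adjusted p = 0.008395). Without congenic pool 1, 14 passed adjusted over the list alone, 13 higher and 1 lower, Pnliprp2 (-0.37). None of the 10 lies on chromosome 17. Between pools of one strain they differed by a median of 0.0725, but the call itself favours probes whose pools differ little. Trypsinogens are near-identical copies, so their values are uncertain, and the count of 10 was 5 without congenic pool 1, 6 without congenic pool 2 and 6 without the variance trend.

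Liver transcripts were also higher in the congenic pools. Of 8 measured members, 1 rose, 0 fell and 7 did not pass, and 3 passed adjusted over the list alone. Alb, which encodes serum albumin, rose 2.86-fold (1.52 ± 0.15, limma adjusted p = 0.0202), and Ahsg (1.22 ± 0.16) and Fgg, a fibrinogen chain (1.28 ± 0.22), passed over the list alone. All 8 differences were positive, with a median of 0.54 (camera adjusted p = 4.671e-06; adjusted p = 0.3591 with an estimated correlation; fry adjusted p = 0.0405). Without congenic pool 1, without congenic pool 2 and without the variance trend, 0 of 8 passed in limma over all probes and between 3 and 4 adjusted over the list alone.

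Skeletal muscle genes were lower in the congenic samples. Of 9 measured members, 3 fell, 0 rose and 6 did not pass, and 8 passed adjusted over the list alone, all lower. Acta1, skeletal alpha-actin, fell by 1.58 ± 0.070 (limma adjusted p = 0.0009033), the myosin light chain Myl1 by 1.74 ± 0.16 and the troponin Tnnt3 by 1.18 ± 0.13. Mb, which encodes myoglobin (-1.77 ± 0.30), Mylpf (-1.08 ± 0.16) and Tnnc2 (-0.90 ± 0.12) did not pass over all probes. The list's median was -1.08 (camera adjusted p = 2.781e-09; adjusted p = 0.3403 with an estimated correlation; fry adjusted p = 0.0405). Smooth muscle genes, the contractile programme of the stomach wall, gave 0 of 15 past the threshold in limma, 4 with an unadjusted p under 0.05 and 0 adjusted over the list alone, with a median of -0.046 (camera adjusted p = 0.5079). The count of 3 was 1 without congenic pool 1, 2 without congenic pool 2 and 1 without the variance trend.

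Lists of the stomach's own secretory cells had smaller median differences. The enteroendocrine list, of hormone-secreting cells, had negative differences for 16 of 17 members and a median of -0.16 (camera adjusted p = 0.004552; adjusted p = 0.5232 with an estimated correlation; fry adjusted p = 0.0405). None passed over all probes in limma, 4 had an unadjusted p under 0.05, and the same 4 passed adjusted over the list alone. They were Pcsk1n, a secretory granule protein (-0.93 ± 0.15), the gastrin gene Gast (-0.59 ± 0.099), the ghrelin gene Ghrl (-0.43 ± 0.093) and Chgb (-0.32 ± 0.078). The list-alone count was 1 without congenic pool 1, 2 without congenic pool 2 and 0 without the variance trend. The chief cell list, of pepsinogen-secreting cells, had positive differences for all 5 members and a median of 0.29 (camera adjusted p = 0.004552; adjusted p = 0.5232 with an estimated correlation; fry adjusted p = 0.08091). None passed over all probes in limma, and 2 had an unadjusted p under 0.05 and passed adjusted over the list alone, Rnase1 (0.61 ± 0.11), which the pancreas list also holds, and Bhlha15 (0.29 ± 0.094). That count was 1 without congenic pool 1 or wild-type pool 1 and 0 without congenic pool 2. Cblif had the largest chief cell difference (0.64 ± 0.33), but read 19.02 in wild-type pool 1, against 20.14 to 20.24 on the other arrays. Without that pool the chief cell median was 0.26 and the mean 0.24, against a mean of 0.37 over all arrays. Parietal cells, which secrete acid, had 0 of 14 genes past the threshold in limma and a median of -0.057. Of these, 4 had an unadjusted p under 0.05 and 1 passed adjusted over the list alone, Ezr (-0.51 ± 0.097). Ezr is a gene of chromosome 17, at position 7 in gene order. Pit and neck mucous cells had 0 of 14 genes past the threshold in limma, 1 with an unadjusted p under 0.05 and 0 adjusted over the list alone, with a median of -0.019 and a test direction of up. For the keratinised forestomach lining 0 of 20 passed in limma, 6 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone, with a median of -0.15.

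**Figure D3:**
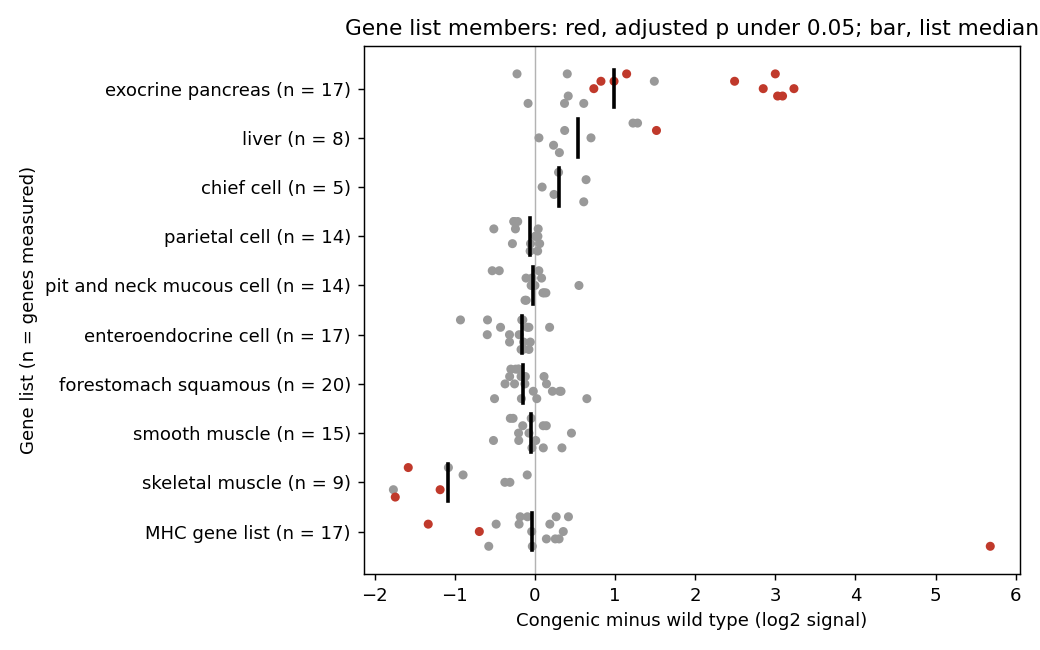
Difference between congenic and wild-type stomach (log2 signal) for each measured member of 10 gene lists; red points passed an adjusted p of 0.05 in limma over all probes, grey points did not, vertical placement within a row only separates points, and black bars are list medians. The medians of exocrine pancreas (0.99) and skeletal muscle (-1.08) lie farthest from 0, and H2-Ob is the single point beyond 5.

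Of 31 lists with at least 5 measured genes, 5 passed in camera with the preset correlation (exocrine pancreas, skeletal muscle, liver, chief cell and enteroendocrine). With an estimated correlation 0 passed in camera, and 3 had an unadjusted p under 0.05. The estimates were -0.025 for exocrine pancreas, -0.053 for skeletal muscle, -0.064 for liver, -0.049 for enteroendocrine and 0.082 for chief cell. Only chief cell lay above the preset 0.01, so for the others correlation between genes does not account for the larger p-values. With an estimated correlation, camera uses the 2 residual degrees of freedom. In fry, which tests whether a list's genes moved on balance one way, 5 passed: exocrine pancreas, skeletal muscle, liver, enteroendocrine, and immediate early and stress genes, but not chief cell. Of the 26 lists that did not pass in camera, 24 had 0 members past the threshold in limma. Immediate early and stress genes had a median of -0.069 (camera adjusted p = 0.422, fry adjusted p = 0.0405), and 8 of 20 passed adjusted over the list alone, 2 higher and 6 lower. Among them were Dusp1 (-0.46 ± 0.079), Fos (-0.34 ± 0.071) and Jun (0.40 ± 0.080). Dusp1 is a gene of chromosome 17, at position 105 in gene order. Of the intestinal list 4 of 10 passed adjusted over the list alone, with Fabp1 (0.57 ± 0.091) and Apoc3 (0.88 ± 0.19) higher and Anpep (-0.49 ± 0.10) and Rbp2 (-1.27 ± 0.34) lower. Of the circadian clock list 2 of 9 did, Usp2 (-0.51 ± 0.12) and Nfil3 (0.74 ± 0.17). In each of 3 further lists 1 gene did: Ghrl among 8 motility receptors and peptides, Fabp4 (-0.45 ± 0.087) among 8 adipose genes and Ndufa1 (-0.48 ± 0.080) among 33 genes of oxidative phosphorylation. Oxidative phosphorylation had the smallest adjusted p of the lists that did not pass (camera adjusted p = 0.06004; median -0.096).

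The other lists had no member past the threshold over all probes in limma and none adjusted over the list alone. Their medians were 0.12 for secretory and endoplasmic reticulum stress genes, -0.10 for cholesterol synthesis, -0.062 for fatty acid oxidation and 0.088 for the interferon response. They were 0.0059 for the cell cycle, 0.0050 for glutathione and xenobiotic enzymes, 0.074 for interstitial cells of Cajal and 0.048 for enteric neurons and glia. They were 0.029 for fibroblasts, -0.18 for endothelium, -0.17 for mast cells and -0.025 for macrophages and dendritic cells. Between 0 and 3 members of each of these lists had an unadjusted p under 0.05. Glycolysis had a median of -0.023, a mean of 0.18 and a test direction of up, with 1 of 11 members at an unadjusted p under 0.05. Its median was 0.0084 and its mean 0.025 without wild-type pool 1, whose values of Gapdh and Hk1 lay below those of the other 3 arrays (16.05 against 18.88 to 19.09, and 12.97 against 14.61 to 14.69). Without that pool Gapdh differed by 0.20 and Hk1 by -0.017. In lists too small to test, Jchain of B and plasma cells differed by 0.12 ± 0.10 and Hba-a1 of erythroid cells by -0.21 ± 0.072, and neither passed. Of the 3 measured genes of T and natural killer cells, Cd5 fell, and Nkg7 (0.43 ± 0.23) and Cd2 (-0.65 ± 0.25) did not pass. No endocrine pancreas gene was measured on all arrays.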

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

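Both results here come from probes with blanks, which the comparisons left out, and were chosen after the data were seen. On both congenic arrays and on no wild-type array, 419 probes had a value, against 198 probes with the opposite pattern. The other 4 ways of picking 2 of the arrays gave between 207 and 306 probes. Wild-type arrays had more blanks among dim probes. Where the other arrays averaged 10 to 12, blanks made up 8.44% and 6.38% in wild-type pools 1 and 2. In congenic pools 1 and 2 they made up 3.86% and 3.88%. The counts of 419 and 198 therefore do not tell strain differences in single genes from more blanks on the wild-type arrays. Of the probes with values in the congenic pools alone, 9 of the 172 placed on a chromosome lie on chromosome 17, and of those with values in the wild-type pools alone, 9 of 93. For the other 4 pairs of arrays it was between 1 of 86 and 10 of 130. Among the 7904 placed probes with values on all arrays, 383 lie on chromosome 17.

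H2-Ea, the alpha chain of a class II antigen-presenting molecule, had a mean of 12.84 ± 0.13 log2 (SD, n = 2 pools) in the congenic pools and no value in the wild-type pools. It had the second highest mean among named probes with values in the congenic pools alone.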

How the results depend on the processing

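The fit allowing 1 blank per probe was chosen after seeing the data. The 40 named genes that passed kept their direction in every setting that tested them. Of 432 results of these genes across settings, 324 stayed past the threshold and 108 did not, and 12 genes passed in every setting that tested them (Acta1, Cela2a, Cela3b, Chil3, Cpa1, Ctrb1, D17H6S56E-5, Decr2, Dynlt1b, H2-Ob, Reg1 and Taf11). The count of 64 probes was 64 after quantile normalization, 65 after median centring, 51 without the probes below the median level, 68 with 1 blank allowed and 94 with a robust variance. It was 20 without the mean-variance trend, 110 at an adjusted p of 0.1, and 244 at an unadjusted p of 0.01 with at least 1.5-fold. The 20 on chromosome 17 became 8 without the trend and 69 at an unadjusted p of 0.01. Leaving out 1 pool gave between 15 and 168 calls and between 6 and 16 on chromosome 17, with 1 residual degree of freedom and the lone pool assumed to vary like the others. Without wild-type pool 2, 55 of the 168 were among the 64. The replicate number as a block left 35 calls, 34 of them among the 64, and 9 on chromosome 17, with 1 residual degree of freedom. The labels do not say that the numbers pair the pools, and the deviations of congenic pool 1 and wild-type pool 1 from their strain means correlated at -0.064 across probes. With windows of 40 genes the highest chromosome 17 window stayed above every other chromosome in each refit, with a permutation p of at most 0.005994. With windows of 20 genes it was 40% against at most 25% elsewhere (permutation p = 0.011), and with windows of 80 genes 28.8% against 13.8% (permutation p = 0.001, the smallest that 1000 shuffles can give). Camera called between 4 and 6 lists in the refits, against 5, and 0 with an estimated correlation. Among named genes that did not pass, 8 differences changed sign when 1 pool was left out, with ranges of -0.37 to 0.0655 for Cck, -0.13 to 0.40 for Vipr1, -0.45 to 0.024 for Aif1, -0.017 to 1.67 for Hk1, -0.20 to 0.0455 for Pcsk1, -0.0125 to 0.23 for B2m, -0.082 to 0.36 for Tff2 and -0.25 to 0.076 for Clps. For these changes the cause was not tested. Not run were an offset on the log scale, since the values were already logged, any alternative for Glp1r, which had 1 value, and the list test with blanks. Low signal limits what was compared, since blanks concentrate there.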

Other observations

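The tests of explanations and the counts of partly blank probes in this part were chosen after the results were seen. Several transcripts had values in both pools of one strain and in neither pool of the other. In the congenic pools these included the pancreatic genes Ctrl (12.82), Gp2 (11.65) and Spink1 (11.51), the liver-expressed Cyp3a44 (11.69) and Saa2, an acute-phase protein (11.97 log2). In the wild-type pools they included Eno3, the muscle enolase (13.26), Csrp3 (10.84) and Ttn, which encodes titin (10.67 log2). The genes named for both strains were picked by tissue after their values were seen. By mean among named probes with values in the wild-type pools alone, Eno3 ranked 1, Csrp3 14 and Ttn 19. By mean among those of the congenic pools alone, Ctrl ranked 3, Saa2 6, Cyp3a44 13, Gp2 15 and Spink1 18. Among T and natural killer cell genes with blanks on some arrays, 7 had more congenic than wild-type values and 0 the opposite (Cd3d, Cd3e, Cd3g, Cd8b1, Klrd1, Gzmb and Prf1). Against the 57.7% of all partly blank probes with more congenic values, the exact binomial p was 0.0238, not adjusted for the 36 lists whose blanks were counted. In the same list Cd5 fell, and Cd2 differed by -0.65 ± 0.25 (limma adjusted p = 0.3001), so its members did not share a direction. The Cd5 probe read 17.84 in wild type and 16.60 in the congenic pools, against 11.98 and 11.34 for Cd2. Whether that probe reads Cd5 alone was not examined, so its fall does not decide the direction for T cells.

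Genes past the threshold were concentrated on chromosome 17. A scatter without order over the genome is argued against by the window test (permutation p = 0.0003). That test does not tell closeness within the chromosome from a higher share over all of it. CAST sequence under the probes, which could lower hybridisation, is argued against for the 8 that were higher in the congenic pools, if the probes were designed on C57BL/6J sequence. For the 12 that were lower it cannot be told apart from lower expression, because no CAST sequence was used here. A difference in expression between the CAST and C57BL/6J forms of these genes stays open and was not tested: probe and CAST sequences, or a cross in which each allele is read separately, would be needed to decide. As background, C57BL/6 mice are known not to express H2-Ea because of a promoter deletion.

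Pancreas and liver transcripts were higher in the congenic pools, and pancreas and liver tissue in these samples is a candidate explanation. A rise of the stomach's chief cells is not decided, although that list's median was 0.29 (SD 0.24) against 0.99 for the exocrine pancreas. All 5 chief cell differences were positive. Cblif and Chia1 read 20.22 and 20.59 in the congenic pools, and exocrine genes near that level, Pla2g1b and Clps, differed by 0.42 and -0.086. The dimmer chief cell genes Bhlha15 and Pga5 differed by 0.29 and 0.24, and Rnase1, in both lists, by 0.61. The medians compare genes of unlike brightness. Of the exocrine pancreas, endocrine pancreas and liver probes with blanks on some arrays, 8 had more congenic and 1 more wild-type values. The exact binomial p was 0.0887 against the share over all partly blank probes, with genes taken as independent. By list the counts were 6 and 0 for exocrine pancreas, 1 and 0 for liver and 1 and 1 for endocrine pancreas. The p depends on including the endocrine list, which had no gene measured on all arrays, so this test does not decide. The brightest measured members were Pla2g1b, at log2 levels of 19.98 in the congenic pools and 19.57 in wild type, which passed adjusted over the list alone, and Clps, at 19.66 and 19.74, which did not. Of the 17 members, Clps and Pnliprp2 alone were not higher in the congenic pools, and 2 of the 17 measured exocrine genes (Rnase1 and Clps) stand in another list too. Carried tissue and a strain difference in these genes cannot be told apart here.

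Skeletal muscle transcripts were lower in the congenic pools, and less striated muscle in these samples is a candidate explanation. Less muscle of every kind is argued against by the smooth muscle list, whose median was -0.046 (SD 0.25) against -1.08. Of the skeletal muscle probes with blanks on some arrays, 2 had more wild-type and 0 more congenic values (exact binomial p = 0.1785), too few to decide. Acta1, the brightest member in wild type, had log2 levels of 14.52 in the congenic and 16.10 in the wild-type pools. The amount of striated muscle and a strain difference in its genes cannot be told apart here.

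The real split of the arrays called 64 probes, and the highest of the others called 0 in limma, with 200 and 290 probes at an unadjusted p under 0.05. In the other splits each group held 1 congenic and 1 wild-type pool, so strain differences there widened the spread within groups. Few calls were thus built in, and 200 and 290 lie below the 673.8 that chance would give. The 0 is therefore no measure of false calls. In 1 of the 3 ways to divide 4 arrays into 2 and 2 as many were called, and 3 splits are too few for a share under 0.05.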
